A study of Mus musculus with 8 samples.

How the data were processed

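Gene expression was measured in the striatum of 4-week-old male mice with 1-colour microarrays, 4 from R6/2 mice and 4 from wild-type (WT) controls. R6/2 mice carry a transgene with the first exon of the human huntingtin gene and an expanded CAG repeat, and are a widely used model of Huntington's disease. Per the labels' protocols, total RNA was extracted with a phenol reagent, purified on columns and labelled with the dye Cy3 by the array maker's standard protocol. Each sample had its own array and scanner file. The labels call the samples replicates without saying that each came from a separate animal, so the p-values measure only the spread between these samples, which may be partly technical.

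Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1. The intensity values in these deposited files are the mean spot signal, the median local background, and a processed signal. Per the file headers, the authors' processed signal was spatially detrended, and spots near background were given a surrogate value. No scaling between arrays had been applied to these intensities. The authors also deposited a table of the whole series. The log2 values that the authors deposited in it were normalized by taking the log2 of the processed signal and subtracting a constant per array. This was found from the values: the constant left 75.0% of the table's values below it on each of the 8 arrays, while the normalization itself is not stated in the header of the authors' table. Its column medians lay between -3.49 and -3.27, the scale was log2, no centring of genes across arrays was seen, and the direction was R6/2 relative to WT for 100% of its values. The authors' p-values in that table come from an unpaired t-test with asymptotic p and Benjamini-Hochberg correction, per the file headers, with both thresholds set so that every probe was kept. The authors' fold values there are ratios without a sign, with the direction in a separate column.

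The values analysed here were log2 of the processed signal minus the log2 of each array's 75th percentile over all non-control spots. Spots marked as non-uniform or as population outliers were left out, and the spots of each probe were averaged. The array held 55681 non-control probes. Of these, 26762 were named through a transcript accession and 5056 through a gene number in the GRCm38.p6 gene table, which was used for names only. A further 2011 kept the symbol of the scanner file, 21852 had no gene symbol, and 2214 symbols were updated. A probe was tested when it was well above background on at least 4 of the 8 arrays, whatever their genotype, which left 35121 probes and 17744 named genes. Differences between R6/2 and WT were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted over all tested probes by the Benjamini-Hochberg method. A probe was called at an adjusted p under 0.05. A gene was represented by its tested probe of highest mean signal. Errors of differences are standard errors (SE) from limma, and those of group means are standard deviations (SD) over 4 arrays. Where a probe was not well above background on any array of a genotype, its fold is given as an approximate lower bound on the processed signal. The bound sets the brighter genotype's mean against the dimmer one's, with each dim array's value taken as the higher of the lowest signal among its probes well above background and the probe's own signal. It makes no allowance for sampling error and uses the lowest such signal, so the true fold may be smaller. Probe positions are those of the scanner files, on mouse build mm9.

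Before the data were examined, the main test, the 27 gene lists, the alternatives and the rule for naming genes were fixed. The lists comprised 5 primary lists, 9 secondary lists and 13 lists of markers of cell types and neighbouring regions. The rule named Htt, the 10 largest rises and the 10 largest falls among called genes with a standard symbol whose R6/2 arrays all lay on the same side of the WT arrays, up to 4 called members of each list (or the 2 of smallest p where none was called), the genes of the sex check, and Gm12695 with any called gene within 1 Mb. It passed over 41 called genes with predicted or clone names. Some genes that the rule named are not reported here, and remain in the counts of genes. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists, and again with an estimated correlation, with fry and on ranks. With the preset correlation 17 lists were called, with an estimated correlation 0 were (lowest adjusted p = 0.239), by fry 8 and on ranks 18. The count of list members that pass when adjusted over the list alone is given beside the count over all probes.

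The procedure was tested on simulated data with the 35121 probes of this comparison, of which 200 were changed. It recovered 37.3% of probes changed 1.5-fold, 65.7% of those changed 2-fold and 86.4% of those changed 4-fold, and 8 of its 134 calls were false. Recovery depends on the share of probes that truly change, so these rates need not hold in the data. Of 200 simulated lists without a shift, 8 had an unadjusted p under 0.05. The simulated probes varied independently of each other, so this does not test the preset correlation on genes that vary together. In the data the estimated correlation was 0.55 for the list of projection neuron identity genes. The number of arrays limits the precision of every value.

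All 8 arrays lay on 1 slide and were scanned in 1 session. The genotypes lay in separate columns of the slide, so slide column and genotype cannot be told apart. Each replicate number had its own row of the slide, per the file headers. Deviations from the genotype means were correlated between WT and R6/2 arrays with the same number (0.133 to 0.356), while the highest correlation between arrays with different numbers was 0.0472. All 8 arrays correlated best with their own number in the other genotype. The numbers were therefore taken to pair the samples, from the data and the slide position. The main fit, fixed beforehand, leaves this pairing out, and a fit with the replicate number as a block was run as an alternative.

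The other alternatives were normexp background correction with an offset of 50, quantile normalization, a 75th percentile over probes detected on all arrays, no filter or a stricter filter on dim probes, a trended robust variance, array weights, reducing each gene to 1 probe or to the mean of its probes before the fit, the authors' normalized values, and leaving out each array in turn. The methods' unpaired t-test, and the block without both replicate 3 samples, were added after the data had been seen. Chromosomes were compared with Fisher's exact test, and differences of list means between genotypes with exact permutation tests, all 2-sided. The permutations do not keep the replicate pairs.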

Results

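Striatal RNA of 4-week-old male R6/2 mice was compared with that of WT controls, 4 arrays per genotype. The comparison asks how gene expression in the striatum, the brain region most affected in Huntington's disease, differed between the genotypes at this age. Between 61.5% and 67.7% of probes were well above background on each array, the 75th percentile of the processed signal lay between 434 and 486, and 0 spots were saturated. Arrays of the same genotype correlated at 0.983 to 0.992 across genes. The Y-linked genes Ddx3y and Eif2s3y were above background on all 8 arrays and Xist on 0, as the label male requires. In R6/2 minus WT, the log2 differences were 0.31 for Ddx3y (adjusted p = 0.109), 0.31 for Eif2s3y (adjusted p = 0.0817), 0.33 for Uty (adjusted p = 0.422) and -0.18 for Kdm5d (adjusted p = 0.826). Of the 2 tested probes of Uty, 1 was called.

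Htt, the mouse gene whose human counterpart supplies the transgene, had a log2 difference of 0.01 ± 0.07 (SE, n = 4 per genotype; adjusted p = 0.961), and its sign turned without WT 1, WT 3 (-0.03) or R6/2 2 (-0.02). Its probe, on chromosome 5 at 35251949 to 35252008, lies far from the first exon and so checks nothing about the transgene. Gm12695 on chromosome 4, the gene in which the R6/2 transgene is reported to have integrated, separated the genotypes completely. Its probe (96390578 to 96390637) was well above background on all 4 R6/2 arrays and on 0 WT arrays. The approximate bound for Gm12695 on the processed signal was 14.8-fold higher in R6/2, with a fitted log2 difference of 6.20 ± 0.11 (SE, n = 4 per genotype; adjusted p = 2.5e-07). The replicate block kept the call of Gm12695 (adjusted p = 7.25e-04), and normexp background correction reduced its difference to 2.15. Of the 8 other genes tested within 1 Mb, among them Hook1, Fggy and 4 Cyp2j genes, 0 were called.

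Most genes that differed were lower in R6/2. Of 17744 genes tested, 339 were called, 259 lower and 80 higher, and 249 of them differed by at least 1.5-fold (207 lower, 42 higher). The called probes numbered 529 of 35121, and 5977 probes had an unadjusted p under 0.05. Of all genes tested, 14.4% had their 4 R6/2 arrays on 1 side of all 4 WT arrays, which chance gives for 2.86%. All 339 called genes did, which the test's selection of differences large against their spread favours. Of the 101 called genes with more than 1 tested probe, 33 had every probe called, and 0 had probes called in both directions. The count moved by over 1.5 times when any array but WT 3 was left out: it was 117 without WT 1, 87 without WT 2, 327 without WT 3, 81 without WT 4, 141 without R6/2 1, 87 without R6/2 2, 81 without R6/2 3 and 132 without R6/2 4. With the replicate number as a block, 182 genes were called (35 higher, 147 lower, 160 by at least 1.5-fold), of which 134 were among the 339. In the table deposited by the authors, an adjusted p under 0.05 was given for 144 probes, 59 up and 85 down in R6/2. Of these, 140 were tested here and 106 were also called here.

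Among called genes with a standard symbol, the 10 largest falls by fitted difference included genes of several secreted and cell-surface proteins. They were Mup18 (-3.58 ± 0.37, log2 difference ± SE, n = 4 per genotype) and Mup17 (-3.24 ± 0.37), which encode major urinary proteins, Ly6d (-3.27 ± 0.36), a lymphoid surface antigen, and Wnt8b (-3.07 ± 0.51), a Wnt ligand. Next came Sec14l3 (-2.96 ± 0.40), a lipid transfer protein, Il2rb (-2.85 ± 0.32), a subunit of the interleukin-2 receptor, and Myl4 (-2.64 ± 0.29), a light chain of myosin. Tmprss6 (-2.36 ± 0.27), a membrane serine protease, Zp1 (-2.32 ± 0.21), a zona pellucida glycoprotein, and Crh (-2.29 ± 0.21), the corticotropin-releasing hormone, completed the 10. Adjusted p-values of these genes ran from 0.00725 for Crh and Zp1 to 0.0337 for Wnt8b. Mup18, Mup17, Wnt8b and Il2rb were not well above background on any R6/2 array. On the processed signal their approximate bounds were 3.44-fold, 1.92-fold, 3.96-fold and 4.33-fold lower. These bounds lie below the folds of Myl4 (6.24), Tmprss6 (5.14) and Crh (4.88), which were above background on all arrays, and below that of Ryr1 (4.60), a called gene outside the 10, so neither the order nor the membership of the 10 is settled. Ly6d was well above background on 1 of 4 R6/2 arrays, so its fitted size is uncertain too. The Mup genes are near-identical paralogs whose probes may share signal. The second tested probe of Sec14l3 had a log2 difference of -0.40. With the replicate block the calls of Wnt8b (adjusted p = 0.0821) and Tmprss6 (adjusted p = 0.0583) were lost. With normexp background correction the falls of dim genes shrank, to -0.73 for Mup18, -0.53 for Mup17 (adjusted p = 0.0560), -0.69 for Wnt8b, -0.74 for Il2rb, -1.10 for Ly6d, -1.17 for Sec14l3, -0.81 for Zp1 and -1.55 for Tmprss6.

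Among called genes with a standard symbol, the 10 largest fitted rises included genes of cilia and of cell-surface receptors. They were Mgarp (1.47 ± 0.16, log2 difference ± SE, n = 4 per genotype), a mitochondrial protein, Cfap206 (1.29 ± 0.19), a component of motile cilia, Tshr (1.28 ± 0.24), the thyrotropin receptor, and Cd2 (1.10 ± 0.15), a lymphocyte adhesion molecule. They were followed by Tnnt2 (0.99 ± 0.16), the cardiac troponin T, Ifit1 (0.98 ± 0.18), an interferon-induced gene, Robo1 (0.96 ± 0.15), a receptor for the axon guidance cue Slit, Enkur (0.91 ± 0.16), a protein of cilia, Smim24 (0.90 ± 0.10), a small membrane protein, and Kcnh8 (0.88 ± 0.11), a potassium channel. Adjusted p-values ran from 0.0102 for Smim24 to 0.0489 for Ifit1. Mgarp and Tshr were not well above background on any WT array. On the processed signal their approximate bounds were 2.51-fold and 1.73-fold higher. The bound of Tshr lies below the fold of Kcnh8 (1.84), so its place among the 10 is not settled. The other tested probe of Robo1 had a log2 difference of 0.18. With the replicate block the calls of Cfap206 (adjusted p = 0.0611), Tshr (0.0783), Cd2 (0.0538), Tnnt2 (0.0508), Robo1 (0.0510) and Enkur (0.0733) were lost. With normexp the rises of Mgarp (0.32, adjusted p = 0.0511) and Tshr (0.24, adjusted p = 0.159) lost their calls, and those of Cfap206 (0.65), Cd2 (0.42), Ifit1 (0.51), Enkur (0.56) and Kcnh8 (0.25) shrank. Of the 45 named genes that were called, 17 kept the call in all 8 fits that left out 1 array and 9 in none of them, among these Tshr, Ifit1, Upb1, Nptx2, Kcnh3, Grin2a, Onecut2 and Dcx. For Smim24, Kcnh8, Pdyn, Nptx2 and Grin2a, 1 of 2 tested probes was called.

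Genes that mark striatal projection neurons, the main cell type of this tissue, were lower in R6/2 as a group. Of the 40 identity genes tested, all 40 had a negative difference, 14 fell over all probes, and 32 fell when adjusted over the list alone. The median difference was -0.46 (adjusted p = 7.3e-24 with the preset correlation, and adjusted p = 0.239 with an estimated correlation). Over all alternatives the list's adjusted p ran from 4.9e-27 to 0.239. The sodium channel subunit Scn4b fell by 1.23 ± 0.15 on the log2 scale (SE, n = 4 per genotype; adjusted p = 0.0137), which is 2.35-fold. Rgs14 (-0.90 ± 0.10, adjusted p = 0.0102), a regulator of G protein signalling, Arpp21 (-0.90 ± 0.10, adjusted p = 0.0104), a cAMP-regulated phosphoprotein, and Kcnip2 (-0.61 ± 0.07, adjusted p = 0.0127), a potassium channel subunit, also fell. Of the 3 tested probes of Arpp21, 1 was called. Among genes chosen after their values were seen, the signalling genes Ppp1r1b (-0.73, adjusted p = 0.0291), Pde10a (-0.99, adjusted p = 0.0246), Adcy5 (-0.89, adjusted p = 0.0262) and Cnr1 (-1.07, adjusted p = 0.0409) fell. The replicate block ended the calls of Pde10a (adjusted p = 0.0649), Adcy5 (0.0509) and Cnr1 (0.0508). On the same arrays the mean of 29 genes expressed by all neurons, a list written after the data had been seen, differed by -0.05 ± 0.07 (SE, n = 4 per genotype; exact permutation p = 0.486), with 0 genes called. The identity genes fell by 0.47 ± 0.10 more than these (SE; exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give).

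**Figure D1:**
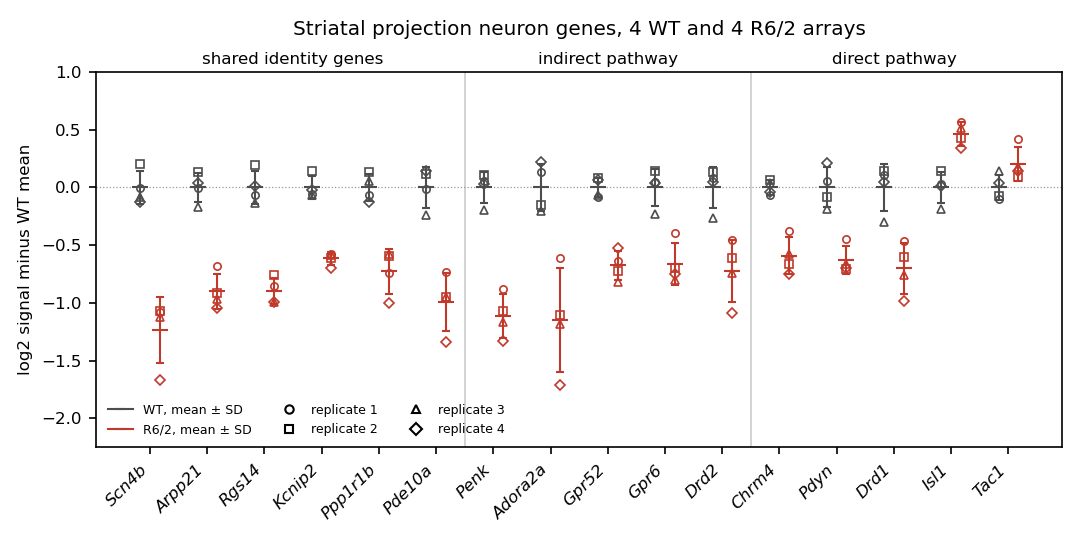
Log2 signal minus the WT mean of projection neuron genes on each of the 4 WT and 4 R6/2 arrays, with the mean ± SD per genotype and a symbol per replicate number. Scn4b, Arpp21, Rgs14, Kcnip2, Penk and Gpr52 lie lower on every R6/2 array than on any WT array, while the differences of Isl1 (0.46, adjusted p = 0.0555) and Tac1 (0.21, adjusted p = 0.328) were positive.

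As a list, markers of indirect pathway projection neurons fell further than those of the direct pathway. Of 13 indirect pathway markers tested, 5 fell over all probes, 9 fell when adjusted over the list alone, and the median was -0.66 (adjusted p = 2.3e-07, and adjusted p = 0.239 with an estimated correlation). Penk, the precursor of enkephalin, fell by 1.11 ± 0.11 (SE, n = 4 per genotype; adjusted p = 0.0102). The orphan receptors Gpr52 (-0.68 ± 0.09, adjusted p = 0.0170) and Gpr6 (-0.66 ± 0.12, adjusted p = 0.0431) and the enzyme gene Upb1 (-0.95 ± 0.17, adjusted p = 0.0419) fell too. Of genes chosen after their values were seen, the adenosine receptor Adora2a fell (-1.15, adjusted p = 0.0499) and the dopamine receptor Drd2 did not pass (-0.72, adjusted p = 0.0615). Of 13 direct pathway markers, 2 fell over all probes, and 3 fell and 1 rose when adjusted over the list alone. Their median was -0.13 (adjusted p = 0.0898, adjusted p = 0.499 with an estimated correlation, and adjusted p = 0.0432 without R6/2 1). The 2 were the muscarinic receptor Chrm4 (-0.59 ± 0.09, adjusted p = 0.0294) and Pdyn (-0.63 ± 0.11, adjusted p = 0.0371), the precursor of dynorphin. The dopamine receptor Drd1, chosen after its value was seen, had a difference of -0.70 (adjusted p = 0.0573, and adjusted p = 0.0418 without WT 3), and the tachykinin gene Tac1 of 0.21 (adjusted p = 0.328). The indirect list mean was lower than the direct list mean by a further -0.41 ± 0.06 in R6/2 (SE, n = 4 per genotype; exact permutation p = 0.0286, the smallest possible), a comparison chosen after the values were seen. Drd1 and Drd2 had similar differences, however, and how well each list marks its own neurons was not tested. The replicate block ended the calls of Upb1 (adjusted p = 0.0593), Gpr6 (0.0590), Adora2a (0.0789), Chrm4 (0.0663) and Pdyn (0.0617), and normexp reduced the falls of Gpr52 (-0.40) and Chrm4 (-0.32). Over all alternatives the adjusted p ran from 3.7e-08 to 0.239 for the indirect list and from 0.0432 to 0.499 for the direct list.

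Genes of neuronal signalling were lower as well. Of 45 voltage-gated channel genes, 3 fell over all probes, 7 fell when adjusted over the list alone, and the median was -0.20 (adjusted p = 5.0e-07, and adjusted p = 0.239 with an estimated correlation). Among them were the potassium channels Kcnh4 (-0.78 ± 0.11, SE, n = 4 per genotype; adjusted p = 0.0229) and Kcnh3 (-0.77 ± 0.14, adjusted p = 0.0443). Of 34 glutamate and GABA receptor genes, 3 fell over all probes, 6 fell when adjusted over the list alone, and the median was -0.15 (adjusted p = 4.3e-05, and adjusted p = 0.239 with an estimated correlation). Among these were Gabrd (-0.74 ± 0.08, adjusted p = 0.0102), the delta subunit of the GABA-A receptor, and the NMDA receptor subunit Grin2a (-0.45 ± 0.08, adjusted p = 0.0481). Of 24 neuropeptide and peptide signal genes, 22 had a negative difference, and Crh was the 1 that fell over all probes. The median was -0.58, and 9 fell when adjusted over the list alone (adjusted p = 2.2e-07, and adjusted p = 0.239 with an estimated correlation). The replicate block ended the calls of Kcnh4 (adjusted p = 0.0617) and Grin2a (0.0600).

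Immediate early genes, which neuronal activity induces, and cholesterol synthesis genes were lower as groups by the preset test, with few members past the threshold. Of 29 immediate early genes, the synaptic pentraxin Nptx2 fell (-1.02 ± 0.19, SE, n = 4 per genotype; adjusted p = 0.0499, and adjusted p = 0.0612 with the replicate block), while its second tested probe had a difference of -0.40. The median was -0.30, and 5 fell when adjusted over the list alone (adjusted p = 7.3e-04, and adjusted p = 0.502 with an estimated correlation). This list stood high in WT 3, with a mean centred log2 signal of 0.70 against 0.23 or less on the other 7 arrays, and without WT 3 its adjusted p was 0.199 (0.127 with array weights). Over all alternatives it ran from 4.18e-06 to 0.502. Of 25 cholesterol synthesis genes, 0 were called by limma, 1 fell when adjusted over the list alone, and the median was -0.12 (adjusted p = 0.00355, and adjusted p = 0.517 with an estimated correlation, with a range over the alternatives of 1.48e-06 to 0.517). Srebf2, the transcription factor of sterol synthesis, was among the genes of smallest p there (-0.36, adjusted p = 0.0724).

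Genes of protein quality control and energy metabolism differed little. Of 31 proteasome subunits, 29 had a positive difference, 0 were called in limma or when adjusted over the list alone, and the median was 0.10 (adjusted p = 0.0204, and adjusted p = 0.697 with an estimated correlation). The proteasome call was lost without WT 3 (adjusted p = 0.603), R6/2 1 (0.0522) or R6/2 4 (0.0565), and the smallest p-values were those of Psmc4 (0.14, adjusted p = 0.370) and Psmb3 (0.15, adjusted p = 0.442). Of 28 transcription and chromatin regulators tied to mutant huntingtin, 0 were called, 2 rose when adjusted over the list alone, and the median was 0.11 (adjusted p = 0.00847, and adjusted p = 0.499 with an estimated correlation). Nfya, a subunit of a CCAAT-binding transcription factor, was 1 of them (0.52, adjusted p = 0.0780). The 28 heat shock genes (median 0.09, adjusted p = 0.118) and the 26 genes of the unfolded protein and integrated stress response (median 0.10, adjusted p = 0.178) had 0 called members over all probes or adjusted over the list alone. Both lists reached an adjusted p of 0.0366 without R6/2 3. Their smallest p-values were those of Hspa2 (0.29, adjusted p = 0.0895) and Dnajb5 (-0.28, adjusted p = 0.284), and of Trib3 (-0.86, adjusted p = 0.106) and Atf4 (0.26, adjusted p = 0.108). Of 49 nuclear-encoded oxidative phosphorylation genes 0 were called over all probes or adjusted over the list alone, with a median of 0.02, a mean of -0.01 and a test direction of lower (adjusted p = 0.744, and adjusted p = 0.00503 without WT 3). Its direction turned without WT 1 (adjusted p = 0.395), WT 4 (0.725) or R6/2 3 (0.705). The coactivators Ppargc1a (-0.35, adjusted p = 0.0719) and Ppargc1b (-0.49, adjusted p = 0.113) had its smallest p-values. Of 23 homeobox and developmental regulators tested among 66 on the array, Onecut2 fell over all probes and when adjusted over the list alone (-0.42 ± 0.07, adjusted p = 0.0416, and adjusted p = 0.0676 with the replicate block), with a list median of 0.08 (adjusted p = 0.440).

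**Figure D2:**
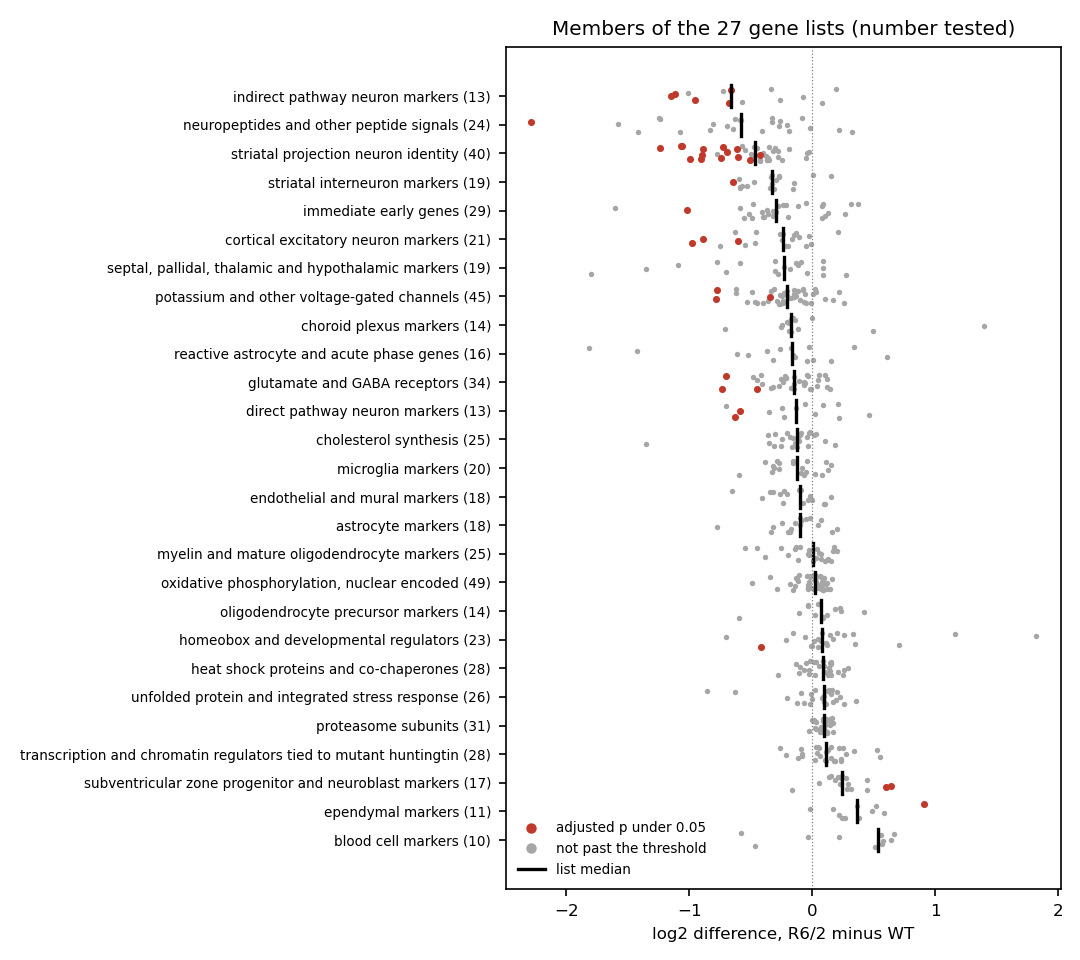
Log2 differences (R6/2 minus WT) of the tested members of the 27 gene lists, a point per gene, with called genes in red and a bar at each list's median; the number tested follows each name. Medians run from -0.66 for the indirect pathway markers to 0.53 for the blood cell markers.

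Lists of markers of other neurons moved in the direction of the projection neuron genes. Whether their signal in striatal RNA came from those other neurons was not tested. Of 19 striatal interneuron markers, Th, the enzyme that makes the dopamine precursor, fell (-0.64 ± 0.09, SE, n = 4 per genotype; adjusted p = 0.0259, and adjusted p = 0.0668 with the replicate block). The interneuron median was -0.33, and 2 fell when adjusted over the list alone (adjusted p = 3.2e-06, and adjusted p = 0.239 with an estimated correlation). Of 21 cortical excitatory neuron markers, 3 fell over all probes and 3 when adjusted over the list alone, with a median of -0.24 (adjusted p = 4.3e-05, and adjusted p = 0.256 with an estimated correlation). These were the pentraxin Nptx1 (-0.98 ± 0.13, adjusted p = 0.0185), the calmodulin-binding protein gene Nrgn (-0.61 ± 0.08, adjusted p = 0.0219) and Rspo1 (-0.89 ± 0.13, adjusted p = 0.0259, and adjusted p = 0.0610 with the replicate block), a secreted activator of Wnt signalling. With normexp the fall of Nptx1 shrank to -0.39. Of 19 markers of septum, pallidum, thalamus and hypothalamus 0 were called over all probes or adjusted over the list alone, with a median of -0.23 (adjusted p = 0.00978, and adjusted p = 0.239 with an estimated correlation), and the smallest p-values were those of Peg10 (-1.09, adjusted p = 0.0966, and adjusted p = 0.0434, past the threshold, with the replicate block) and Lhx9 (-0.70, adjusted p = 0.160).

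Markers of the ventricle wall moved the other way. Of 17 progenitor and neuroblast markers of the subventricular zone, 16 had a positive difference, and Sox11 (0.64 ± 0.07, SE, n = 4 per genotype; adjusted p = 0.0104) and Dcx (0.60 ± 0.11, adjusted p = 0.0489), both genes of immature neurons, rose over all probes and when adjusted over the list alone. The median was 0.24 (adjusted p = 6.99e-04, and adjusted p = 0.470 with an estimated correlation). Both tested probes of Sox11 and 1 of 2 of Dcx were called, and the replicate block ended the call of Dcx (adjusted p = 0.0701). Of 11 ependymal markers, 10 had a positive difference and Enkur rose over all probes and when adjusted over the list alone. The ependymal median was 0.36 (adjusted p = 0.00398, adjusted p = 0.499 with an estimated correlation, and adjusted p = 0.0567 without WT 2). The array R6/2 3 had a progenitor list mean of -0.17, within the WT range of -0.24 to -0.04.

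Markers of glia and vessels had few or no genes past the threshold. The 25 myelin genes had a median of 0.01 and a mean of -0.04 (adjusted p = 0.491), and 0 were called, although 1 fell when adjusted over the list alone. The direction of the myelin test turned without WT 1 (adjusted p = 0.466) or R6/2 4 (0.445). The 14 oligodendrocyte precursor genes had a median of 0.07 (adjusted p = 0.454, and adjusted p = 0.0327 without R6/2 4), with 0 called by either adjustment. Their smallest p-values were those of Ermn (-0.55, adjusted p = 0.0532, with a second probe at 0.18) and Mobp (-0.45, adjusted p = 0.30), and of Cacng4 (-0.60, adjusted p = 0.193) and Enpp6 (0.43, adjusted p = 0.304). The 18 astrocyte genes, with 0 called over all probes or adjusted over the list alone, had a median of -0.10 (adjusted p = 0.0301, and adjusted p = 0.499 with an estimated correlation), and their call was lost without WT 3 (0.114), WT 4 (0.0774) or R6/2 4 (0.146). The 20 microglia genes, with 0 called over all probes or adjusted over the list alone, had a median of -0.12 (adjusted p = 0.0267, and adjusted p = 0.499 with an estimated correlation), and their call was lost without WT 3 (0.199), WT 4 (0.0636) or R6/2 4 (0.0756). The smallest p-values were those of Slc1a2 (-0.32, adjusted p = 0.0897) and Aldoc (-0.20, adjusted p = 0.182) among astrocyte genes, and of Cd68 (-0.27, adjusted p = 0.105) and Itgam (-0.28, adjusted p = 0.146) among microglia genes. The 18 endothelial and mural genes had a median of -0.10 (adjusted p = 0.0932) with 0 called over all probes and 1 that fell when adjusted over the list alone. Their adjusted p was 0.0313 without WT 1, 0.0240 without WT 2, 0.00599 without R6/2 3 and 0.923, with the direction reversed, without WT 3. Tagln (-0.65, adjusted p = 0.0614, and adjusted p = 0.0477 without WT 3) and Tie1 (-0.34, adjusted p = 0.337) had the smallest p-values.

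The remaining lists varied more between arrays than between genotypes. The 16 reactive astrocyte and acute phase genes tested had a median of -0.17 (adjusted p = 0.214), and the 14 choroid plexus genes a median of -0.18 (adjusted p = 0.518), with 0 called by either adjustment. The smallest p-values were those of Aspg (-0.61, adjusted p = 0.124) and Gfap (0.34, adjusted p = 0.168), and of Tmem72 (-0.71, adjusted p = 0.481) and Sostdc1 (0.49, adjusted p = 0.788). The 3 tested probes of Gfap, the intermediate filament of astrocytes, ran from 0.34 to 2.33, and 1 of them was called. Choroid plexus means ranged from -0.99 on WT 4 to 1.17 on WT 3 among WT arrays, and from -0.91 to 0.47 among R6/2 arrays. The acute phase mean was 0.99 on WT 3 and 0.10 or less on the other 7 arrays, and without WT 3 its direction reversed (adjusted p = 0.577). The direction of the choroid plexus list reversed without WT 1 (adjusted p = 0.721), WT 3 (0.582) or R6/2 2 (0.575). The 10 blood cell genes had a median of 0.53 (adjusted p = 0.0257, adjusted p = 0.499 with an estimated correlation, 0.0770 without WT 1 and 0.0862 without WT 4), with 0 called over all probes and 1 that rose when adjusted over the list alone. Its globin genes Hba-a1 (0.56, adjusted p = 0.0710, and adjusted p = 0.0425 without R6/2 4) and Hbb-bs (0.58, adjusted p = 0.202) had the smallest p-values.

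**Figure D3:**
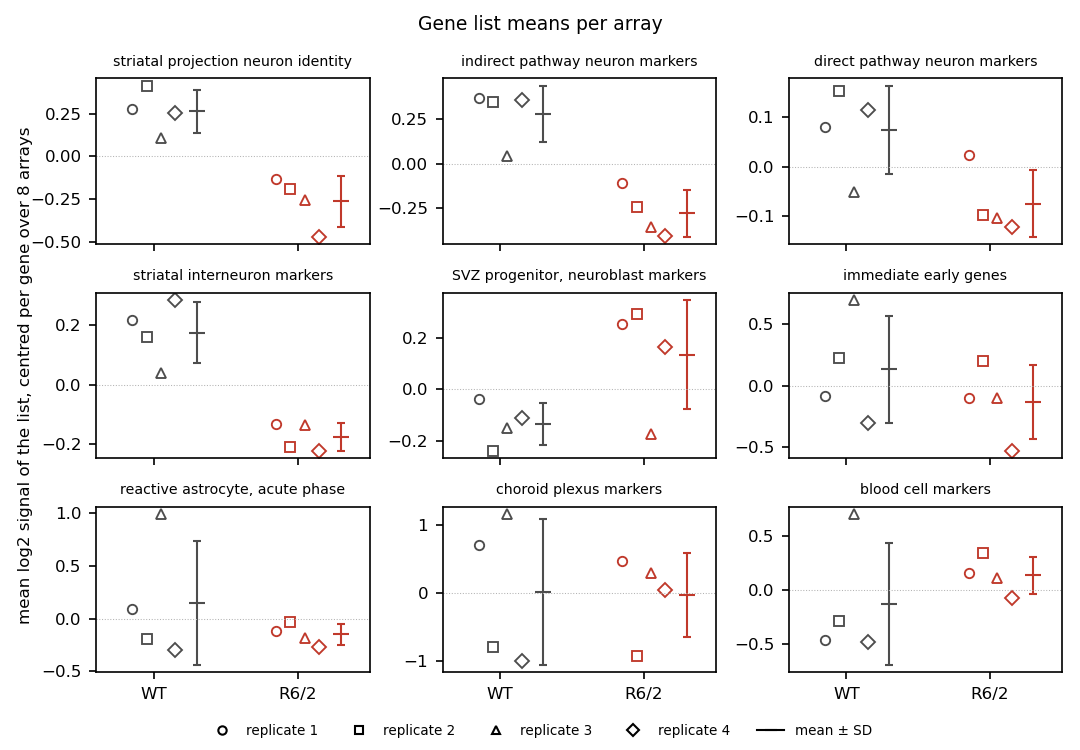
Mean log2 signal of 9 gene lists on each array, each gene centred over the 8 arrays, with the mean ± SD per genotype (4 arrays each). Projection neuron identity runs from 0.11 to 0.41 in WT and from -0.47 to -0.13 in R6/2, whereas WT 3 holds the highest value of the immediate early (0.70), acute phase (0.99), choroid plexus (1.17) and blood cell (0.70) lists.

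Called genes were not concentrated on any chromosome. The lowest adjusted p over the chromosomes was 0.762 for all called genes and 0.345, on chromosome 4, for those of at least 1.5-fold (Fisher's exact test, unadjusted p = 0.0164). Within 20 Mb of Gm12695, 0 of 196 other genes were called, which allows up to 1.86% at the 95% level, against 1.93% of genes elsewhere in the genome (Fisher's exact p = 0.0571). On the rest of chromosome 4 it was 27 of 902 (2.99%; Fisher's exact p = 0.00867, a comparison chosen after the values were seen). The nearest called gene lay 24.3 Mb away. Of 6 Mup genes tested on chromosome 4, 4 fell: Mup4 (-2.26), Mup17, Mup18 and Mup19 (-2.10). Mup4 and Mup19 were well above background on 1 of 4 R6/2 arrays, so their fitted sizes are uncertain. Their probes lie between 59969824 and 61439555, 34.951 Mb or more from Gm12695.

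**Figure D4:**
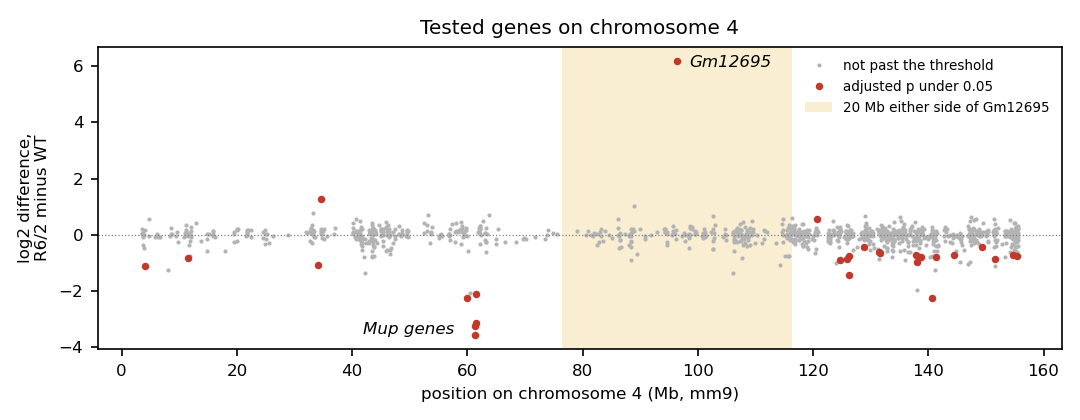
Log2 difference (R6/2 minus WT) of each tested gene on chromosome 4 against its probe position in Mb on build mm9, called genes in red, with 20 Mb either side of Gm12695 shaded. Gm12695 lies at 6.20 and 0 of the 196 other genes in the shaded window are called, while the Mup genes lie lower in R6/2 outside it.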

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

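The tests of blood, neutrophils and choroid plexus in WT 3 were chosen only after that array's values had been seen, and so were the tests of cell composition. Over both genotypes together, 214 values were examined for an array far from the other 3 of its genotype. Of these, 17 (7.94%) had such an array, where chance gives about 5%, and 6 of the 17 were in WT 3.

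Projection neuron identity genes were lower in R6/2, and 3 technical explanations were set against a change within these neurons. Fewer neurons in the R6/2 samples would lower genes of all neurons alike, but the identity mean fell by 0.47 ± 0.10 more than the pan-neuronal mean (SE; exact permutation p = 0.0286, the smallest possible). Dilution by glia would raise glial genes, but the mean shift of the myelin, astrocyte, microglia and endothelial lists (81 genes) was -0.12 ± 0.08 (SE; exact permutation p = 0.229). Tissue with more cortex, septum, pallidum, thalamus or hypothalamus would raise their markers, but the higher of those list medians was -0.23. Where striatal neurons express such markers too, a fall within them could hide added tissue, so these medians cannot exclude it. Tissue with more ventricle wall stays open, since the ependymal (0.36) and subventricular zone (0.24) medians were higher in R6/2. A loss of projection neurons alone had no test of its own. As they are the main cell type here, their loss would also lower genes of all neurons. The pan-neuronal mean differed by -0.05 ± 0.07 (SE), which argues against such a loss as the whole account of the identity fall. A smaller loss stays open. Slide column, which cannot be told apart from genotype, stays open too. So does, as a hypothesis, lower expression of identity genes within the neurons that carry the transgene.

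WT 3 stood apart from the other arrays in several acute phase genes, picked after their values were seen. In WT 3, 158 genes were more than 2-fold above all 7 other arrays, against 6 to 72 for each of the others, and relative to the mean of the other WT arrays Lcn2, an iron-binding acute phase protein, was 5.75 higher on the log2 scale, Lrg1 5.79 and S100a8 4.41. Blood would bring haemoglobin, but the median haemoglobin gene, Hbb-bt, was 0.157 higher, within the range of the other WT arrays. However, Hbb-b2 (1.45 higher) and Hbb-bs (0.62 higher) lay above every other WT array. Neither was highest in WT 3 once R6/2 arrays were included, at -0.07 for Hbb-b2 and -0.42 for Hbb-bs relative to the highest other array. Choroid plexus tissue was argued against, since the median marker in WT 3 was -0.112 relative to WT 1, where Lcn2 was low. Neutrophils may be a source and stay open, with 2 of 10 neutrophil genes, Fpr1 (2.63) and Retnlg (1.51), more than 1 above every other array, and an inflamed or stimulated animal was not tested.

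Other list means of WT 3 lay far from those of the other 3 WT arrays. The differences from the mean of those arrays were -0.31 for the indirect pathway markers, 0.31 for the homeobox genes, -0.31 for the proteasome subunits, 0.49 for the endothelial markers and 1.11 for the blood cell markers. Robo1 was 0.42 higher in WT 3. In WT 2, Upb1 was 0.49 higher than the mean of the other WT arrays, Aspg 0.36 and Rspo1 0.38. In WT 4, Tmprss6 was at -1.04 relative to the others. In R6/2 4, Crh was 0.65 higher than the mean of the other R6/2 arrays, while Scn4b was at -0.58. In R6/2 3, Gfap was 0.36 and Tie1 0.47 higher, while Tnnt2 was at -0.42 and the proteasome mean at -0.14. In R6/2 2, Htt was 0.11 higher.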

How the results depend on the processing

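The methods' unpaired t-test, and the replicate block without replicate 3 of both genotypes, were chosen after seeing the data. Slide and scan blocks were not run, since all 8 arrays share 1 slide and 1 scan. Signal over background limits the sizes of dim genes: with normexp, 19 of the 45 named genes that were called had under 2/3 of their size. The called named genes kept their direction in all 576 values under other settings, of which 126 lost the call, and in all 360 values with 1 array left out, of which 176 lost it. The 34 named genes other than Htt that were not called gained a call in 36 of 441 values under other settings and in 3 of 272 with 1 array left out. Htt, counted apart, was not called in any setting. With normexp these included Srebf2 (adjusted p = 0.0350), Hspa2 (0.0298), Ppargc1a (0.0267), Ermn (0.0216), Tagln (0.0292) and Hba-a1 (0.0281), and of the genes chosen after their values were seen Drd1 (0.0237), Drd2 (0.0337) and Isl1 (0.0251) also passed. The replicate block called 1 of the 34, Peg10 (0.0434). The cause of the changes below was not tested, except that leaving out arrays lowers the number of samples.

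The number of changed genes was 652 with normexp (197 higher, 455 lower), 84 without a filter on dim probes (11 higher, 73 lower, 82 by at least 1.5-fold), 681 with a trended robust variance (207 higher, 474 lower) and 610 with array weights (172 higher, 438 lower). It was 553 with a representative probe (159 higher, 394 lower), 529 with the mean of probes (149 higher), and 180 with the methods' unpaired t-test (114 lower, 95 by at least 1.5-fold). The replicate block gave 182 (35 higher, 147 lower, 160 by at least 1.5-fold) and changed no list call. It ended the calls of 20 of the 45 called named genes and gave 1 of the 34 others a call, and changed no other call among them. The block without replicate 3 gave 1 (1 higher, 0 lower, 1 by at least 1.5-fold), Gm12695. With 1 array left out the ranges were 81 to 327 changed, 8 to 63 higher, 68 to 264 lower and 79 to 239 by at least 1.5-fold. Quantile normalization (368), the percentile over detected probes (394), the filter on all arrays (445) and the authors' values (317) stayed within 1.5 times of 339. The median log2 difference over all tested probes lay within 0.04 of 0 in each setting.

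With an estimated correlation all 17 list calls were lost, with an adjusted p of 0.239 for the identity, indirect pathway, channel, receptor, neuropeptide, neighbouring region and interneuron lists and 0.256 for the cortical list. It was 0.470 for the progenitor list, 0.499 for the transcription, astrocyte, microglia, ependymal and blood cell lists, 0.502 for immediate early genes, 0.517 for cholesterol synthesis and 0.697 for the proteasome. By fry 9 calls were lost: immediate early genes (0.270), cholesterol synthesis (0.276), proteasome (0.479), transcription (0.0823), astrocyte (0.215), microglia (0.235), ependymal (0.215), blood cell (0.226) and progenitor (0.0823) lists. On ranks the endothelial list was called (0.0464).

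Without a filter the heat shock list was called (0.0454) and the directions of the homeobox (0.869) and oxidative phosphorylation (0.949) lists reversed, as did that of oxidative phosphorylation with quantile normalization (0.704). With array weights the calls of immediate early genes (0.127), proteasome (0.131), astrocyte (0.0848) and microglia (0.106) lists were lost and the choroid plexus list reversed (0.926). With the block without replicate 3 the calls of immediate early genes (0.254), proteasome (0.0779) and microglia (0.0996) lists were lost, and the oligodendrocyte precursor (0.783), acute phase (0.580) and choroid plexus (0.506) lists reversed.

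With 1 array left out the adjusted p ranged from 0.0432 to 0.163 for the direct pathway, 4.18e-06 to 0.199 for immediate early genes, 0.0366 to 0.295 for heat shock, 0.0366 to 0.363 for the unfolded protein response, 0.00261 to 0.603 for the proteasome and 0.00503 to 0.983 for oxidative phosphorylation. It ranged from 0.0660 to 0.723 for myelin, 0.0327 to 0.923 for oligodendrocyte precursors, 0.00853 to 0.146 for astrocytes, 0.0660 to 0.577 for acute phase genes, 0.00150 to 0.199 for microglia and 0.00599 to 0.923 for endothelium. It ranged from 2.49e-04 to 0.0567 for ependyma, 0.0660 to 0.721 for choroid plexus and 9.40e-04 to 0.0862 for blood cells. The log2 difference of Htt ranged from -0.032 to 0.036, that of Sostdc1 from -0.12 to 1.04 and that of Kdm5d from -0.34 to 0.18. Htt also reversed with normexp (-0.0029), array weights (-0.010) and the block without replicate 3 (-0.023), and Kdm5d with array weights (0.083) and the block without replicate 3 (0.15).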

Other observations

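Genes of the striated muscle sarcomere and triad, whose proteins contract and couple excitation to calcium release, were lower in R6/2. Of 46 tested, 10 fell and 1, Tnnt2, rose (21.7% lower against 1.41% of other genes; Fisher's exact test, adjusted p = 5.69e-09). Mybpc3, a myosin-binding protein, fell by 1.58 ± 0.12 (SE, n = 4 per genotype; adjusted p = 0.0061), and Ryr1, the calcium release channel of skeletal muscle, by 2.20 ± 0.21 (adjusted p = 0.00901), which is 4.60-fold. Myl4, Myh2 (-1.84) and Myh8 (-1.11) also fell. The 6 families compared here, the pan-neuronal list, and all tests below except those of the sequence near the transgene, of haplotypes and of the splits of the 5 primary lists were chosen only after the results had been seen. The family p-values describe the same calls that guided the choice of families, so they are not independent evidence. They are adjusted over these 6 families only and treat genes as independent.

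Regulators of G protein signalling, which shorten receptor signals, had 4 of 17 genes lower (adjusted p = 2.73e-04): Rgs4 (-1.06), Rgs14, Rgs11 (-0.85) and Rgs9 (-0.74). Of these, Rgs4, Rgs14 and Rgs9 belong to the projection neuron identity list, so the family is not separate evidence. Of 12 acetylcholine receptor genes, 3 fell (adjusted p = 0.00123): Chrna4 (-0.86), Chrna6 (-0.67) and Chrm4, which is also a direct pathway marker. Of 21 integrin subunits, 3 fell (adjusted p = 0.00505): Itga5 (-1.22), Itga11 (-1.03) and Itga9 (-0.96). Of 45 protocadherins, 2 rose, Pcdhb9 (0.77) and Pcdh10 (0.41), and 0 fell by limma. Of 366 zinc finger genes, 2 rose and 2 fell. The family tests compare the share of genes that fell (adjusted p = 0.220 for the zinc finger genes), and shares that rose were not compared.

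Muscle tissue in the WT samples may account for the fall of sarcomere genes. Of 9 abundant skeletal muscle genes sought, 7 were tested. The median of these 7 was -0.42 with a standard error of 0.16 across genes, against a median of -1.03 for the sarcomere genes called lower. The differences of the 7 ran from -0.93 to 0.34, and 0 of the 7 were called by limma. These values leave muscle tissue and a change within striatal cells open.

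Sequence from the strain in which the transgene arose, inherited with it, may change genes near Gm12695. The upper 95% limit of the share called within 20 Mb was 1.86%, below the 2.99% on the rest of chromosome 4. The rest of the chromosome includes the Mup genes, whose probes may share signal. The limit lay close to the 1.93% of genes called elsewhere in the genome (Fisher's exact p = 0.0571). These values argue against an excess of called genes near Gm12695, while changes too small to be called stay open.

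Genes that were on in some animals and off in others may mark inherited strain haplotypes. Genes were counted when a gap of at least 2 on the log2 scale parted low from high arrays. The gap had to exceed the spread on either side, with at most 4 low arrays, and genes parted by genotype were left out. This gave 54 genes. Of 12 pairs of them within 2 Mb, 8 (66.7%) had the same low arrays, against 51 of 1308 pairs (3.90%) on different chromosomes (permutation p = 1e-04, the smallest that 10000 permutations can give). Without the 3 Vmn2r genes, which are paralogs, it was 5 of 9 pairs. Other paralogs were not looked for, so shared probe signal stays possible among the remaining pairs. Animals with the same number may be related: of 24 ways to match WT with R6/2 samples, the numbering of the labels, 1 of 24, gave the highest agreement of on and off states (70.8%, against up to 69.9% for the others).

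Of 35 splits of the 8 arrays into groups of 4, the real split alone, 1 of 35, gave as many changed genes (339, against up to 11 for the others), higher genes (80 against 7), lower genes (259 against 7) and genes of at least 1.5-fold (249 against 11). The same held for the mean shifts of the identity list (0.53 against 0.40) and the indirect pathway list (0.56 against 0.48). For the direct pathway markers 2 splits gave a shift as large (0.15 against up to 0.19), for immediate early genes 12 (0.27 against 0.52) and for cholesterol synthesis 5 (0.17 against 0.24), so chance cannot be excluded for these 3 lists. The 35 splits ignore that equal numbers pair the samples, and the 8 splits that part all 4 pairs are too few for a share under 0.05. Among those 8 the others gave 0 changed genes and shifts of up to 0.34 for identity, 0.12 for the direct pathway, 0.36 for the indirect pathway, 0.26 for immediate early genes and 0.23 for cholesterol synthesis.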
